A study of Homo sapiens with 4 samples.

How the data were processed

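RNA was measured in SCP2 cells, a bone-metastatic single-cell progeny of the triple-negative breast cancer line MDA-MB-231, on Illumina HumanHT-12 V3 bead arrays with 48803 probes. Per the labels, the cells were starved of serum overnight and then kept in serum-free medium for 24 h with or without 100 pM TGFβ. The groups were control (n = 2 arrays) and TGFβ (n = 2 arrays), taken from the sample titles, and each group held a replicate 1 and a replicate 2. Per the labels' protocols, total RNA was extracted with Trizol, cleaned with a column kit that included a DNase step, and turned into biotinylated cRNA with an Ambion MessageAmp kit. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

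The values analysed were the deposited log2 intensities, 1 per probe and array. GenomeStudio and limma are named in the submitters' processing notes, without versions or roles. The log2 scale was read from the range of the deposited values, 4.40 to 15.5, and no label states it. The sorted values of any pair of arrays differed by at most 0.04, the pattern that quantile normalization between arrays leaves. The deposited values were not centred per probe, and the median of each array was 5.04. The background treatment and any offset added before the logarithm are not given in the sources used here, so values near the bottom of the range may be compressed by an unknown amount. Further tables held 24 columns of per-sample values whose array names match no sample label, and those columns were not used here. On inspection, normalized columns held the same sorted values as the deposited log2 columns, but samples were never assigned by values.

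The design fixed before the data were examined started from scanner signals, with normexp background correction, quantile normalization and a filter on detection p-values. Those signals could not be tied to samples by name, so the deposited log2 values, planned as an alternative, became the main values. No further normalization was applied. A probe was tested when its log2 value exceeded 5.5 on at least 2 of the 4 arrays, which kept 16982 probes. This floor replaced the detection filter and was chosen after the values, and the counts of calls at several floors, had been seen. In a group whose arrays all lay at or below the floor, a gene has only a bound, and its change is given as at least a number of folds. The bound sets the mean of the brighter group against the dimmer group's mean, with each dim array taken at the floor or at its own value, whichever was higher. The bound holds on the deposited scale only and not under a larger offset.

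Probe names came from the platform annotation supplied with the values, with symbols updated through gene identifiers to those of the GRCh38.p14 gene table. Of the probes on the array, 28098 had 1 gene symbol, 13 had several and 20692 were unnamed here. A gene was represented by its brightest tested probe among probes with 1 symbol, which gave 10677 genes. Of the 16982 probes tested, 2876 had no symbol.

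Groups were compared in R 4.3.3 with limma 3.58.1, using lmFit and eBayes with default settings, no covariates and a 2-sided moderated test. P-values were adjusted by the Benjamini-Hochberg method over all 16982 probes, and a gene was called at an adjusted p under 0.05. Each probe left 2 residual degrees of freedom, to which the prior shared across probes added 5.31. Errors of group means are standard deviations over 2 arrays, and errors of log2 fold changes are moderated standard errors. The number of arrays limits the precision of every value.

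The test was checked on simulated data built from the probes of this comparison, with 200 changed probes in each of 10 simulations of 16982 probes. It recovered 0% of changes of 0.5 on the log2 scale, 28.9% of changes of 1 and 97.8% of changes of 2. Of the simulated calls, 5.23% were false. Simulated variances that follow the test's own prior would give a share near the threshold by construction. The false and recovered shares therefore hold for the simulated data only and do not check the measured variances. On the measured arrays, eBayes with trend and robust called 273 genes against 117, so the calls depend on the prior assumed. A list shifted by -0.5 was called in 10 of 10 simulations, and 2 of 310 unchanged lists were called. Simulated probes varied independently, whereas the correlation estimated from the data was 0.43 in the shifted list, of mitotic genes. It was 0.77 in the S phase list. The simulation therefore does not show how often lists of correlated genes are called falsely.

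Gene lists, 32 in number and holding 824 genes, were fixed before the data were examined. Of these genes, 592 were tested and 47 had no named probe. Lists were tested with limma's camera on 1 probe per gene with a preset inter-gene correlation of 0.01, 2-sided, and adjusted over the 32 lists. The same lists were tested with the correlation estimated from the data and with fry, which asks whether the genes of a set move one way on balance. With the correlation estimated, camera rests on the 2 residual degrees of freedom. A call lost there need not be lost through correlation between genes. Members of each list were also adjusted over the list alone. That adjustment does not control errors across the 32 lists, and a gene that rose or fell by it alone was not called. The same limma p can pass in 1 list and not in another. CDKN1A had an adjusted p of 0.021 among TGFβ targets and 0.13 among G1 genes.

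Genes were named by a rule fixed in advance. It took 8 genes by name, the 12 largest rises and the 12 largest falls among called genes whose TGFβ arrays both lay beyond both control arrays, and up to 4 called members of each list. Where a list had no called member, up to 2 members with the smallest unadjusted p are given as values. The rule gave 76 genes, 35 of them called. Of the 8 genes fixed by name, 7 were tested, and 1 had no named probe and was not analysed here. Genes outside the rule that appear beside a small count were chosen after their values were seen. The named genes had 23 other tested probes, and all 23 changed in the direction of the probe reported. Of the 13 such probes that belonged to called genes, 8 were called themselves.

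Each alternative changed 1 choice, except that the trended, robust prior switched on both options, and the floor above 6 on all 4 arrays changed both the level and the number of arrays. Those planned in advance were no filter on dim probes, the mean over the probes of a gene, the replicate number as a block, eBayes with trend and robust, each array left out in turn, stricter thresholds and the other list tests. Alternatives added after seeing the data were a log2 value above 6 on all 4 arrays or on at least 2, a floor 0.25 lower, 34 added to every value on the linear scale, and cyclic loess between arrays. Gene order along chromosomes, used in the closing section, came from the GRCh38.p14 gene table.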

Results

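Transcript levels were measured on 4 arrays of SCP2 breast cancer cells, 2 from control cells and 2 from cells treated with 100 pM TGFβ for 24 h after overnight serum starvation. On each array, 34.2% of the probes lay above the floor of 5.5 used here. Across the 16982 tested probes, Pearson's r was 0.991 between the control arrays and 0.991 between the TGFβ arrays. Between a control and a TGFβ array it ran from 0.984 to 0.989. These correlations are across probes, which are not independent replicates. No pair of arrays was identical. The single comparison, TGFβ against control, asks which transcripts TGFβ changes in these cells, and the title of the series puts BMP4, cyclin D1 and stem cell self-renewal at its centre.

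The genes called higher with TGFβ included 8 of 23 tested collagen and matrix genes, 3 of 20 TGFβ targets and 3 of 27 matrix proteases and inhibitors. Those called lower included an activin subunit, a lysyl oxidase relative and an inhibitor of growth factor signalling. The largest rise was in COL6A3, a chain of type VI collagen, from 5.89 ± 0.25 to 9.90 ± 0.87 (log2 value, mean ± SD, n = 2 per group), a 16.2-fold change. Its log2 fold change of 4.02 became 3.40 without TGFβ replicate 2 and 4.63 without TGFβ replicate 1. PMEPA1, a feedback inhibitor of TGFβ signalling, rose 10.1-fold, and TGFBI, a secreted matrix protein first found as a TGFβ-induced gene, rose 9.38-fold. The largest fall on the deposited values was in INHBB, which encodes the activin βB subunit, from 9.74 ± 0.11 to 7.38 ± 0.37, a 5.12-fold change. Genes below the floor with TGFβ have only a bound and could have fallen further. LOXL4, a lysyl oxidase family member, fell 4.37-fold.

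In the limma test, 117 of 10677 genes were called, 68 higher and 49 lower with TGFβ. Of these, 62 were at least 2-fold higher and 44 at least 2-fold lower. At an unadjusted p under 0.05, 1083 of the 10677 genes passed, 497 higher and 586 lower. Unchanged genes pass that threshold by chance at a rate of about 0.05, here and in the counts given for lists. In all 117 called genes both TGFβ arrays lay beyond both control arrays, a separation that the call itself favours. With 2 arrays against 2, such separation arises by chance in 33.3% of unchanged genes, so in uncalled genes it adds little. The smallest absolute log2 fold change among called genes was 0.88, and the median was 1.49 in risen and -1.34 in fallen genes. The median log2 fold change over all genes tested was -0.02. The count fell to 70 genes without control replicate 2 and to 48 genes without TGFβ replicate 2. Without control replicate 1 the balance turned, with 49 genes higher and 72 lower. It rose to 227 with 34 added on the linear scale and to 273 with a trended, robust variance prior.

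Other large rises included TAGLN, which encodes the actin-binding protein transgelin, with a log2 fold change of 3.13 (SE 0.18, adjusted p = 0.0014). MARCHF4, a membrane-bound ubiquitin ligase, rose by 3.02 (SE 0.15, adjusted p = 0.0010). COL4A1 and COL4A2, which encode partner chains of type IV collagen, rose by 3.01 (SE 0.23) and 2.41 (SE 0.26). PDGFB, a platelet-derived growth factor chain, rose by 2.77 (SE 0.26), and FSTL3, a secreted antagonist of activins, by 2.33 (SE 0.19). The non-coding transcript MIR181A2HG rose by 2.27 (SE 0.21) and CSF1R, the receptor for colony-stimulating factor 1, by 2.22 (SE 0.29). CGB5, a chorionic gonadotropin β gene, lay below the floor on both control arrays and was at least 3.95-fold higher with TGFβ on the deposited scale. Its probe is uncertain because the chorionic gonadotropin β genes are nearly identical in sequence. The adjusted p of these genes lay between 0.0010 and 0.021.

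**Figure D1:**
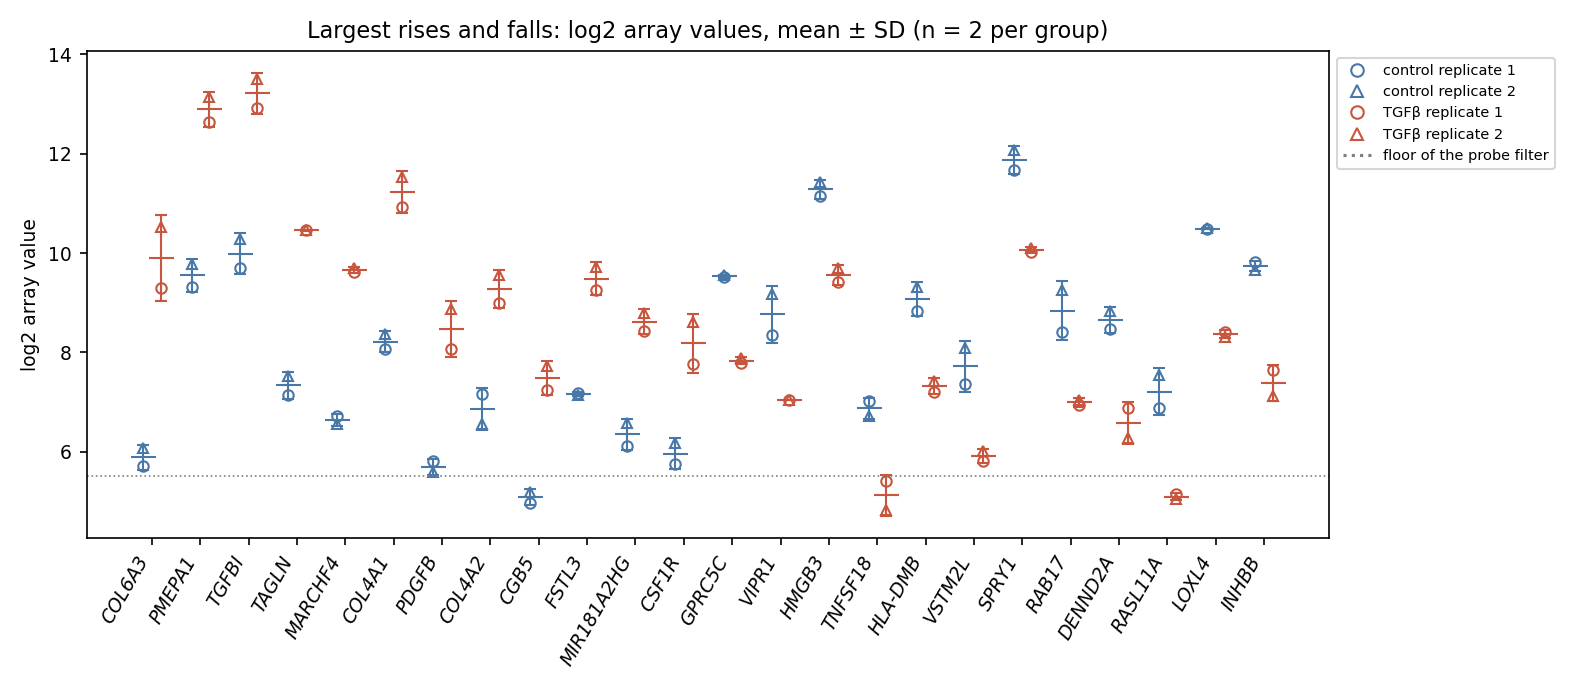
Log2 array values (vertical axis) of the 12 called genes with the largest rises and the 12 with the largest falls, ordered by log2 fold change of the deposited values. CGB5, RASL11A and TNFSF18 have a group below the floor, so their places in this order are uncertain. Circles and triangles are replicates 1 and 2, horizontal bars with whiskers are means ± SD (n = 2 per group), and the dotted line is the floor of 5.5. In each gene both TGFβ arrays lie on one side of both control arrays, and COL6A3 rises from 5.89 to 9.90.

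Among the fallen genes, SPRY1, an inhibitor of receptor tyrosine kinase signalling, went from 11.88 ± 0.27 to 10.06 ± 0.05, a log2 fold change of -1.81 (SE 0.18, adjusted p = 0.0072). HMGB3, a chromatin protein, went from 11.29 ± 0.19 to 9.56 ± 0.19, a log2 fold change of -1.73. HLA-DMB, which helps load peptides on MHC class II molecules, had a log2 fold change of -1.75. RASL11A and TNFSF18 lay below the floor on both TGFβ arrays and were at least 3.27-fold and at least 2.59-fold lower on the deposited scale. DENND2A (-2.07), RAB17 (-1.84), VSTM2L (-1.80), VIPR1 (-1.73) and GPRC5C (-1.70) completed the 12 largest falls by log2 fold change. Of the 2 other GPRC5C probes, 1 was called lower and 1 differed by only -0.06. Without TGFβ replicate 1 or without TGFβ replicate 2, RAB17 and VIPR1 were no longer called, and VIPR1 was also lost with no filter on dim probes.

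BMP4, the ligand named in the title of the series, had a lower level on both TGFβ arrays (8.73 ± 0.34 in control, 7.63 ± 0.34 with TGFβ, n = 2 each). Its log2 fold change was -1.10 (SE 0.23), a 2.14-fold difference, and its adjusted p of 0.104 did not pass the threshold over all probes. Adjusted over the list alone, in the list of BMP ligands, receptors, Smads and antagonists, BMP4 passed with an adjusted p of 0.013. This adjustment does not control errors across the lists. With 34 added on the linear scale, with the trended, robust prior and without control replicate 1 its adjusted p was 0.025, 0.017 and 0.046. Without control replicate 2 and without TGFβ replicate 1 its adjusted p was 0.31 and 0.25, with a log2 fold change of -0.85 and -0.86. CCND1, which encodes cyclin D1, was near the top of the range in both groups (14.57 ± 0.04 in control, 14.54 ± 0.02 with TGFβ). Its log2 fold change was -0.03 (SE 0.15, adjusted p = 0.98), within the spread between replicates, and scanner saturation at this level was not tested.

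Of the other genes fixed by name, SMAD7, the inhibitory Smad, had a log2 fold change of 1.03 (SE 0.21, adjusted p = 0.092). A dimmer SMAD7 probe passed the test with a log2 fold change of 1.25 (SE 0.16, adjusted p = 0.019). CDKN1A, which encodes the cell cycle inhibitor p21, had a log2 fold change of 0.57 (SE 0.15, adjusted p = 0.19). The ID genes, targets of BMP signalling, gave no call: the log2 fold change was -0.53 (SE 0.16) for ID3, -0.21 (SE 0.20) for ID1 and 0.18 (SE 0.17) for ID2. Both TGFβ arrays lay below both control arrays for ID3, and the groups overlapped for ID1 and ID2. ID1 changed sign without control replicate 2.

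**Figure D2:**
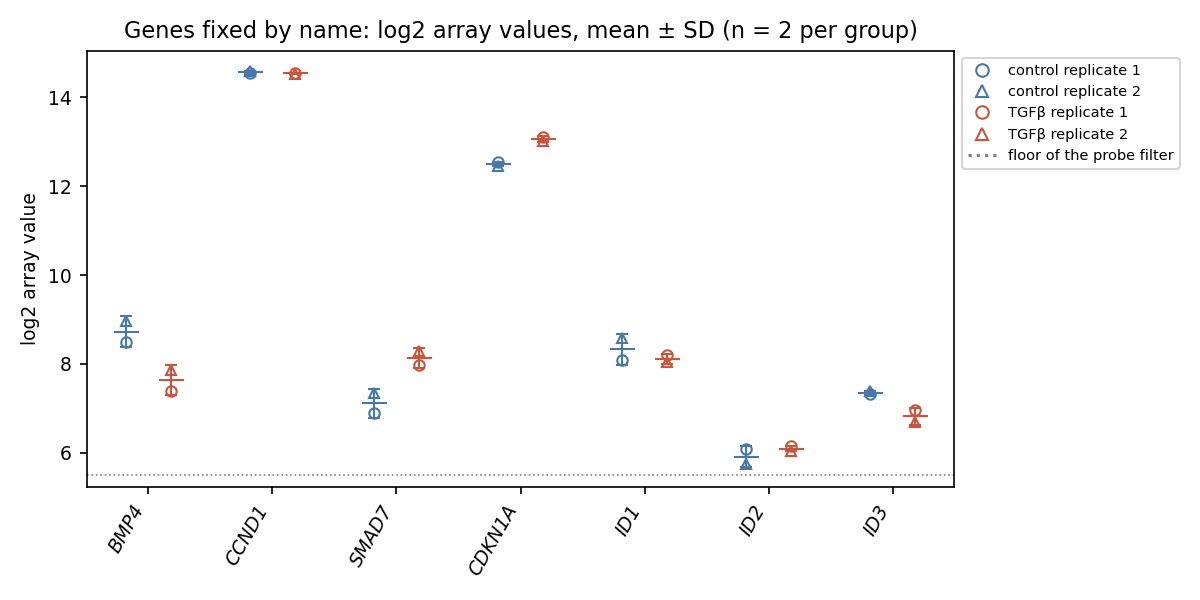
Log2 array values (vertical axis) of the 7 tested genes among those fixed by name, with circles and triangles for replicates 1 and 2 and bars for mean ± SD (n = 2 per group). The dotted line is the floor of 5.5. BMP4 lies lower on both TGFβ arrays (mean 7.63 against 8.73), and CCND1 lies at 14.57 in control and 14.54 with TGFβ.

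The list of collagens and other extracellular matrix genes had 8 of 23 tested members called, all higher, and 9 higher when adjusted over the list alone. COL6A3, TGFBI, COL4A1 and COL4A2 led it. Its median log2 fold change was 0.39 (camera adjusted p = 6.2e-10, but 0.49 with an estimated correlation). It was 0.18 with no filter on dim probes and 0.22 without TGFβ replicate 2. In the list of TGFβ feedback and early target genes, 3 of 20 members rose (PMEPA1, TGFBI and PDGFB), and 8 rose when adjusted over the list alone. The median log2 fold change was 0.23 (camera adjusted p = 8.0e-06, but 0.49 with an estimated correlation), and 0.35 without control replicate 2. Among proteases and protease inhibitors of matrix turnover, 3 of 27 rose, and 9 rose and 2 fell when adjusted over the list alone. Those called were PLAU, the urokinase gene (log2 fold change 1.88, SE 0.18), the metalloproteinase gene ADAM19 (1.81, SE 0.31) and ADAMTS6 (1.65, SE 0.18). The median log2 fold change of that list was 0.24 (camera adjusted p = 3.8e-06, but 0.49 with an estimated correlation). It was 0.44 without control replicate 2, 0.38 without TGFβ replicate 1 and 0.42 with the mean over probes. ADAM19, at an adjusted p of 0.0499, was no longer called with no filter on dim probes, with cyclic loess, with the mean over probes, without control replicate 1 or without TGFβ replicate 2.

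The list of TGFβ and activin ligands, receptors and Smads was called lower, with a median log2 fold change of -0.14 (camera adjusted p = 0.029, but 0.49 with an estimated correlation), or -0.30 without TGFβ replicate 1. Of its 12 tested members INHBB alone fell, also when adjusted over the list alone. The list was not called with no filter on dim probes (median -0.07, adjusted p = 0.42), with a floor 0.25 lower, without control replicate 2 or without TGFβ replicate 2. In the list of BMP ligands, receptors, Smads and antagonists, 1 of 16 members was called, the BMP antagonist gene NOG, which rose by 1.14 (SE 0.17, adjusted p = 0.029). Adjusted over the list alone, NOG, BMP1, CRIM1 and FSTL1 rose and BMP4 fell. The list itself was not called (median 0.07, or 0.04 with its dim gene at its bound, camera adjusted p = 0.13). It was called higher without TGFβ replicate 1 (adjusted p = 0.024), and its median was -0.03 without TGFβ replicate 2. NOG was no longer called without control replicate 1, without control replicate 2 or without TGFβ replicate 2. None of 9 BMP target genes was called by limma, also when adjusted over the list alone, and 1, ID3, was lower at an unadjusted p under 0.05. HEY1 had a log2 fold change of 0.34 (SE 0.16), and the list had a median of -0.21 (camera adjusted p = 0.28).

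Genes of mitosis and the G2/M transition were lower as a list, with all 29 tested members below 0 and a median log2 fold change of -0.37 (camera adjusted p = 6.1e-10, but 0.49 with an estimated correlation). Without TGFβ replicate 2 the median was -0.22 with 27 of 29 below 0, and without control replicate 1 it was -0.31 with 28 of 29 below 0. No member was called by limma, 10 were lower at an unadjusted p under 0.05, and 1, KIF20A, fell when adjusted over the list alone. KIF20A, a mitotic kinesin gene, had a log2 fold change of -0.89 (SE 0.16, adjusted p = 0.062), and the mitotic cyclin gene CCNB2 had -0.58 (SE 0.15). The list of S phase genes was not called (25 tested, median -0.07, camera adjusted p = 0.38), with TK1 at -0.46 (SE 0.19) and RFC4 at -0.25 (SE 0.16). It was called lower without TGFβ replicate 1 (adjusted p = 0.013) and without control replicate 2 (adjusted p = 0.0042). Its median lay above 0 without control replicate 1 (0.10) and without TGFβ replicate 2 (0.08). G1 cyclins, CDKs and CDK inhibitors were not called either (21 tested, median -0.08, camera adjusted p = 0.55). Besides CDKN1A, the smallest unadjusted p there belonged to CDKN2D, with a log2 fold change of -0.51 (SE 0.15). No member of the S phase and G1 lists was called, over all probes or adjusted over the list alone. At an unadjusted p under 0.05, 1 S phase gene was lower, and 2 G1 genes were higher and 2 lower.

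Cholesterol synthesis genes and other targets of SREBP were lower as a list (25 tested, 24 of them below 0, median log2 fold change -0.25, camera adjusted p = 1.4e-04, but 0.61 with an estimated correlation). The interferon-stimulated list (36 tested, median -0.20, camera adjusted p = 0.0049) and the hypoxia and glycolysis list (30 tested, median -0.15, camera adjusted p = 0.0032) were also lower, each with an adjusted p of 0.49 with an estimated correlation. In these lists limma called no member, over all probes or adjusted over the list alone, while 6, 4 and 7 members were lower at an unadjusted p under 0.05. FADS2 and MVD had log2 fold changes of -0.52 (SE 0.15) and -0.52 (SE 0.15). OAS3 and PSMB9 had -0.41 (SE 0.15) and -0.49 (SE 0.15), and NDRG1 and PFKL had -0.61 (SE 0.16) and -0.57 (SE 0.16). The hypoxia median was -0.23 without control replicate 1. The cholesterol list was not called without TGFβ replicate 1 (median -0.14, adjusted p = 0.069), and its median shrank to -0.09 without control replicate 2. The interferon list was not called without control replicate 1 (median -0.15, adjusted p = 0.15) or without TGFβ replicate 2 (median -0.08, adjusted p = 0.19).

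**Figure D3:**
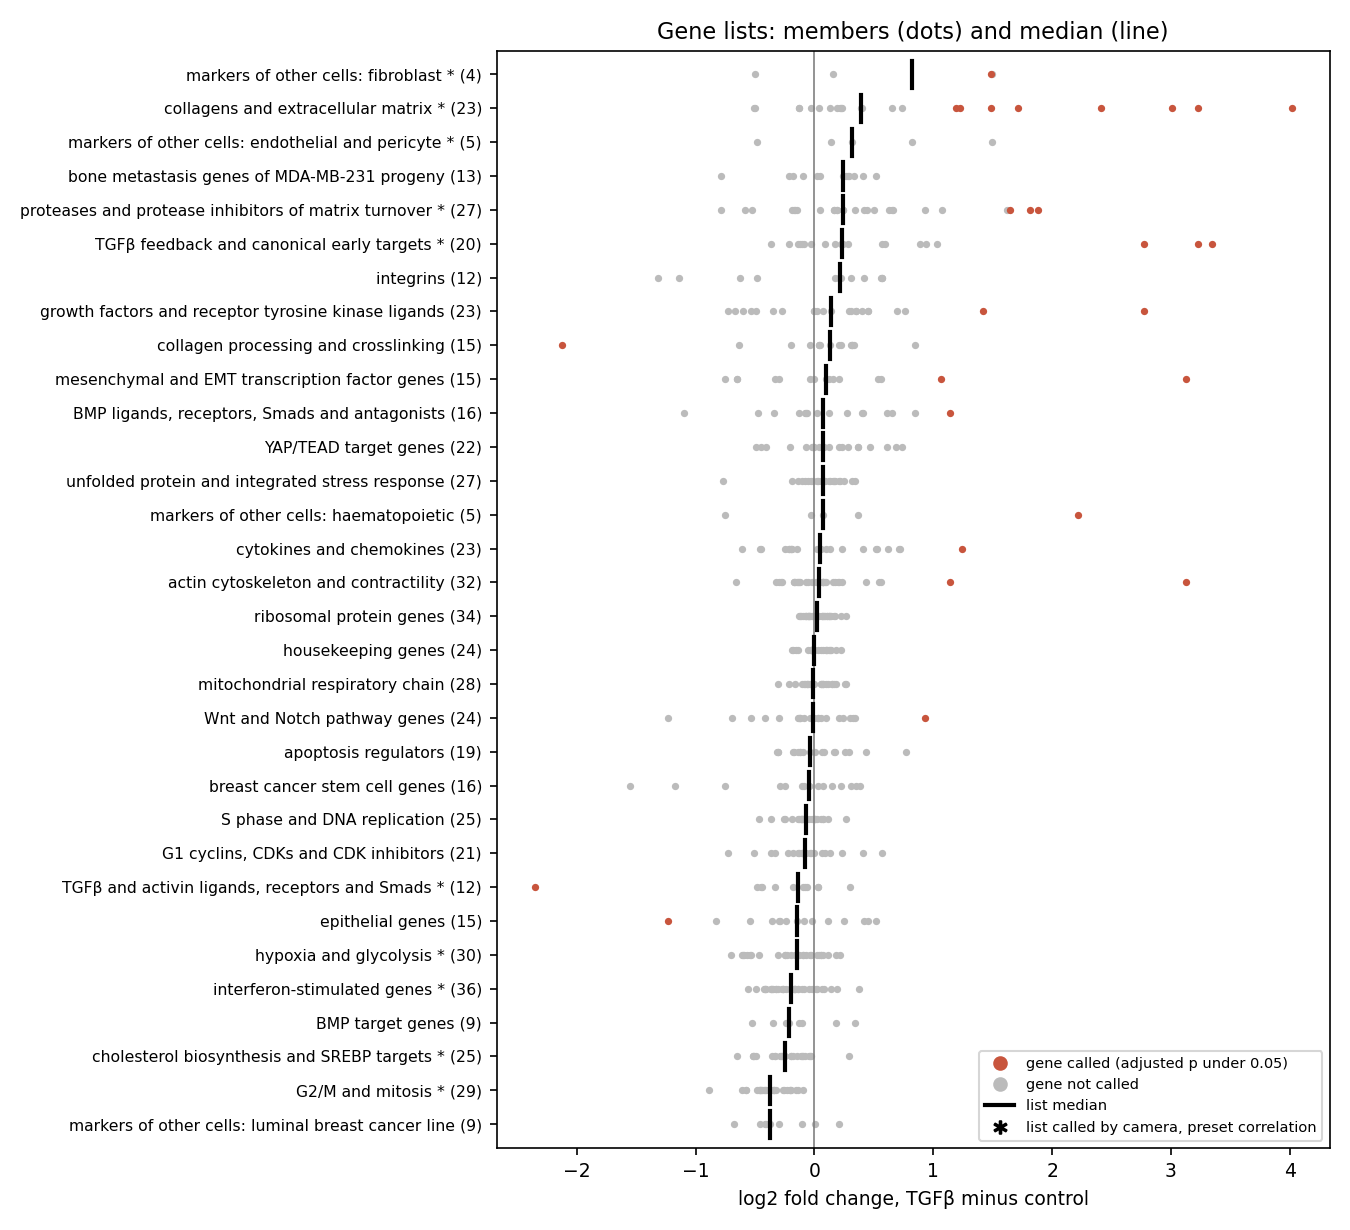
Log2 fold change of TGFβ against control (horizontal axis) for every tested member of the 32 gene lists, with the number tested in parentheses. Each dot is a gene, red where it was called, the black line is the list median, and a star marks a list called by camera with the preset correlation. The collagen and matrix list has 8 red dots on the right, and all 29 mitotic genes lie left of 0.

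The mesenchymal and EMT transcription factor list had 2 of 15 members called, TAGLN and SNAI2. SNAI2, which encodes the transcription factor Slug, rose by 1.07 (SE 0.18, adjusted p = 0.046), and it was no longer called with no filter on dim probes, with cyclic loess, without control replicate 1, without TGFβ replicate 1 or without TGFβ replicate 2. A dimmer SNAI2 probe was not called (1.18, SE 0.26, adjusted p = 0.12). Adjusted over the list alone TAGLN and SNAI2 rose, and FOXQ1 and S100A4 fell. The list was not called (median 0.10, camera adjusted p = 0.28). In the epithelial list, 1 of 15 members fell, the mucin gene MUC1 (-1.23, SE 0.15, adjusted p = 0.019). A dimmer MUC1 probe was not called (-0.75, SE 0.16, adjusted p = 0.10). MUC1 was no longer called without control replicate 2 or without TGFβ replicate 2. KRT8 fell besides it when adjusted over the list alone, and the list was not called (median -0.15, camera adjusted p = 0.28). It was called lower without control replicate 1 (adjusted p = 0.048) and without TGFβ replicate 2 (adjusted p = 0.033), and its median was 0.07 without control replicate 2. Of 32 actin cytoskeleton genes, TAGLN and the tropomyosin gene TPM1 (1.14, SE 0.17) rose, also when adjusted over the list alone. TPM1 was no longer called with the mean over probes, without control replicate 1, without control replicate 2 or without TGFβ replicate 2, and the list was not called (median 0.04, camera adjusted p = 0.24).

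No breast cancer stem cell gene was called among 16 tested, and 3 were lower at an unadjusted p under 0.05. The pluripotency factor gene SOX2 had a log2 fold change of -1.55 (SE 0.29, adjusted p = 0.075). CD24, a surface glycoprotein that is low on breast cancer stem cells, had -1.17 (SE 0.22, adjusted p = 0.070). Both TGFβ arrays lay below both control arrays for SOX2 and CD24, although 33.3% of unchanged genes separate by chance in 1 direction or the other. Both genes fell when adjusted over the list alone. CD24 and SOX2 passed over all probes with 34 added on the linear scale (adjusted p = 0.0098 and 0.030), with the trended, robust prior (0.0030 and 0.015) and without control replicate 1 (0.018 and 0.0031). CD24 also passed with a log2 value above 6 on all 4 arrays or on at least 2. Neither passed when any 1 of the other 3 arrays was left out. The list was not called (median -0.05, camera adjusted p = 0.51). Bone metastasis genes of MDA-MB-231 progeny gave no call among 13 tested (median 0.24, camera adjusted p = 0.16), with IL11 at 0.52 (SE 0.16) and ADAMTS1 at -0.79 (SE 0.23). Adjusted over the list alone none passed, and 1 was higher and 1 lower at an unadjusted p under 0.05. The bone metastasis list was called higher with no filter on dim probes (adjusted p = 0.044) and without control replicate 1 (adjusted p = 0.048).

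In the list of growth factors and ligands of receptor tyrosine kinases, PDGFB and SPHK1 (1.42, SE 0.21) rose of 23 tested. SPHK1 is a sphingosine kinase gene and not itself a growth factor or ligand. In that list 5 rose and 4 fell when adjusted over the list alone. SPHK1 was no longer called without TGFβ replicate 1, without control replicate 2 or without TGFβ replicate 2. The list was not called (median 0.14, camera adjusted p = 0.088), except with the mean over probes and without TGFβ replicate 1 (adjusted p = 0.031 in both). In the cytokine list, IL1A rose by 1.24 (SE 0.19), 1 of 23, and IL32 rose besides it when adjusted over the list alone (median 0.04, camera adjusted p = 0.36). The cytokine list was called higher without TGFβ replicate 2 (adjusted p = 0.016), and its median was -0.14 without TGFβ replicate 1. IL1A was no longer called without control replicate 1 or without TGFβ replicate 2. In the Wnt and Notch list, WNT5B rose by 0.93 (SE 0.15), 1 of 24, and LRP5 and WNT7B fell when adjusted over the list alone (median -0.01, camera adjusted p = 0.79). WNT5B was no longer called when any 1 of the 4 arrays was left out. In the collagen processing list LOXL4 fell, 1 of 15, and BMP1 rose and P3H2 fell besides it when adjusted over the list alone. That list had a median of 0.13, a mean of -0.01 and a camera adjusted p of 0.30.

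Of 12 integrin genes none was called, 2 were higher and 3 lower at an unadjusted p under 0.05, and ITGA10 (-1.32, SE 0.35) and ITGA1 (-1.14, SE 0.27) had the smallest p. Adjusted over the list alone ITGA2 rose and ITGA1, ITGA10 and ITGB2 fell. The median of the list was 0.22, or 0.19 with its dim gene at its bound, and its mean -0.04 (camera adjusted p = 0.38). YAP/TEAD targets (22 tested, median 0.07, camera adjusted p = 0.085) gave no call, with 5 higher and 2 lower at an unadjusted p under 0.05. NT5E (0.74, SE 0.19) and RBMS3 (0.69, SE 0.19) led that list, and none passed when adjusted over the list alone. The YAP/TEAD list was called higher with the mean over probes (adjusted p = 0.031). Unfolded protein and stress response genes (27 tested, median 0.07, camera adjusted p = 0.28) gave no call, with HSPA5 at 0.34 (SE 0.15), CHAC1 at -0.77 (SE 0.18) and 1 member lower at an unadjusted p under 0.05. None passed when adjusted over the list alone. That list was called higher without control replicate 1 (adjusted p = 0.0066) and without TGFβ replicate 2 (adjusted p = 0.0096), and its median was -0.14 without TGFβ replicate 1. Apoptosis regulators (19 tested, camera adjusted p = 0.63) gave no call, with a median of -0.04 and a mean of 0.02. GADD45B (0.77, SE 0.15) was the 1 member to rise when adjusted over the list alone, and BMF had 0.43 (SE 0.17).

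The ribosomal, housekeeping and respiratory chain lists moved little. As fixed, the housekeeping list shared GAPDH, PGK1 and GPI with the hypoxia and glycolysis list, which camera called lower with the preset correlation. Ribosomal protein genes (34 tested, median 0.02, camera adjusted p = 0.37), housekeeping genes (24 tested, median -0.00, camera adjusted p = 0.57) and respiratory chain genes (28 tested, median -0.01, camera adjusted p = 0.57) had no member called, over all probes or adjusted over the list alone. None of their members reached an unadjusted p under 0.05 in the limma test. The median and the mean of the housekeeping and respiratory chain lists differed in sign. RPL4 (0.27, SE 0.15), RPL5 (0.23, SE 0.15), PSMB4 (0.23, SE 0.15), POLR2A (-0.19, SE 0.15), UQCRC1 (0.26, SE 0.16) and NDUFV2 (-0.30, SE 0.17) had the smallest p in these lists.

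Markers of other cell types were measured as lists too. The fibroblast list, with 4 of 15 genes tested, was called higher (median 0.82, or 0.58 with COL1A1 at its bound, camera adjusted p = 0.0495), and so was the endothelial and pericyte list, with 5 of 15 tested (median 0.32, camera adjusted p = 0.048). With an estimated correlation neither passed, at an adjusted p of 0.49 for the fibroblast list and 0.61 for the endothelial list. COL1A1, below the floor on both control arrays, was at least 2-fold higher on the deposited scale, and it was no longer called without control replicate 2 or without TGFβ replicate 2. PDGFRB (1.50, SE 0.30, adjusted p = 0.096) and ROBO4 (0.82, SE 0.16, adjusted p = 0.081) were not called. Adjusted over the list alone, PDGFRB and ROBO4 rose in the endothelial list, and COL1A1 and PDGFRB rose and FBLN1 fell in the fibroblast list. Neither list was called without control replicate 1, with no filter on dim probes, with a floor 0.25 lower or with cyclic loess. The endothelial list was also lost without TGFβ replicate 2 and with a log2 value above 6 on all 4 arrays, and the fibroblast list with 34 added on the linear scale. With no filter the medians were 0.05 for the endothelial list and 0.09 for the fibroblast list, and with a floor 0.25 lower 0.11 and 0.26. The endothelial median was 0.58 without TGFβ replicate 1 and 0.11 without TGFβ replicate 2. In the haematopoietic list, CSF1R rose, 1 of 5 tested, and CD14 fell when adjusted over the list alone (median 0.07, camera adjusted p = 0.36). Markers of luminal breast cancer lines gave no call among 9 (median -0.38, camera adjusted p = 0.071), with CA12 at -0.68 (SE 0.19) and SPDEF at -0.46 (SE 0.20). None of them passed when adjusted over the list alone, and 1 was lower at an unadjusted p under 0.05. The luminal list was called lower without control replicate 1 (median -0.20, adjusted p = 0.048) and without TGFβ replicate 2 (median -0.45, adjusted p = 0.023). Its median was -0.10 with no filter on dim probes.

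In all, camera with the preset correlation called 10 of 32 lists, 5 higher and 5 lower, and 13 lists had an unadjusted p under 0.05. With an estimated correlation camera called 0 lists (lowest adjusted p 0.49, with 1 list at an unadjusted p under 0.05). Correlation alone does not account for every loss. The estimate was 0.0055 for TGFβ feedback and early targets and -0.012 for hypoxia and glycolysis genes, below the preset of 0.01. Fry called 0 lists (lowest adjusted p 0.16, with 7 lists at an unadjusted p under 0.05).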

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

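Alternatives added after seeing the data were the floors other than none, 34 added on the linear scale and cyclic loess, and the floor of 5.5 itself was chosen after seeing the data. The 117 calls (68 higher, 49 lower) became 227 (119 and 108) with 34 added on the linear scale, 273 (140 and 133) with a trended, robust prior, and 25 (19 and 6) at an adjusted p under 0.01. With 1 array left out, 48 to 121 genes were called, 32 to 62 of them higher and 16 to 72 lower, and the balance turned to 49 higher and 72 lower without control replicate 1, with fewer samples and the lone array assumed to vary like the others. The cause of the other shifts was not tested. With the other floors, cyclic loess and the mean over probes the count stayed between 99 and 144. Every tested gene among the 117 kept its direction under all 13 alternatives run, and no named call reversed. Most of these alternatives could not have reversed a call, so this is weak evidence. With both TGFβ arrays beyond both control arrays, leaving out 1 array or adding 34 keeps the sign. The replicate block and the trended, robust prior leave the log2 fold change as it was. BMP4 kept its direction, with log2 fold changes from -1.34 to -0.85 with 1 array left out and -0.98 with 34 added. It passed the threshold there (adjusted p = 0.025), with the trended, robust prior (-1.10, adjusted p = 0.017) and without control replicate 1, and its adjusted p ran from 0.016 to 0.31 over the alternatives. CCND1 ran from -0.052 to 0.00042 and ID1 from -0.46 to 0.032 with 1 array left out, both reversing sign without control replicate 2. The 10 called lists were 7 to 12 under the other settings, and 0 by camera with an estimated correlation and 0 by fry. Of 22 lists not called, 9 were called under at least 1 alternative, and of 41 named genes not called, 15 were. The medians of 13 lists, none of them called, changed sign. With 1 array left out, the median ran from -0.027 to 0.20 for BMP ligands and antagonists, -0.31 to 0.071 for epithelial genes, -0.14 to 0.0079 for G1 genes and -0.22 to 0.099 for S phase genes. It ran from -0.0071 to 0.087 for actin genes, -0.11 to 0.033 for stem cell genes, -0.14 to 0.051 for cytokines, -0.14 to 0.20 for stress response genes and -0.070 to 0.045 for apoptosis regulators. It ran from -0.0053 to 0.054 for ribosomal, -0.010 to 0.049 for housekeeping and -0.027 to 0.038 for respiratory chain genes, and from -0.081 to 0.35 for haematopoietic markers. The median was also -0.035 for actin genes and 0.011 for apoptosis regulators with no filter on dim probes, 0.022 for apoptosis regulators with the mean over probes, 0.0055 for housekeeping genes with cyclic loess and -0.026 for haematopoietic markers with a log2 value above 6 on all 4 arrays. With 34 added, COL6A3 (3.42), PDGFB (2.18), CGB5 (1.65), RASL11A (-1.42), TNFSF18 (-1.13) and COL1A1 (0.91) stayed called, closer to 0. For CGB5, RASL11A, TNFSF18 and COL1A1 these lie below the bounds on their folds, so those bounds hold only on the deposited scale. Dim probes limit the changes that can be read, since 6 called genes lay below the floor in control and 10 with TGFβ.

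With the replicate number as a block, 247 genes were called (127 higher, 120 lower), including all 117, and BMP4 (-1.10, adjusted p = 0.016), CD24 (0.019) and SOX2 (0.019) passed. Among lists, the block ended the call of the fibroblast markers (adjusted p = 0.063) and added that of the luminal markers (adjusted p = 0.027), with medians unchanged. The same-numbered arrays deviated together (r = 0.33 across 16982 probes, which are not independent), but no label says what a number shares, and 2 pairs are too few to settle the pairing. The planned starting points from scanner signals (no background correction, an upper-quartile scaling, a larger offset, the stricter detection filter) were not run. Neither were the authors' normalized table and the slide as a block. No label ties such a column to a sample, and samples were not assigned by values. Normalized columns held the same sorted values as the deposited log2 columns, so that table may be no separate processing.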

Other observations

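The genes and lists of the next paragraphs were chosen after their values were seen. All 7 tested MHC class II genes lay below 0, 2 of them called, with a median log2 fold change of -0.74, and each was lower at an unadjusted p under 0.05. HLA-DMB (-1.75, SE 0.20, adjusted p = 0.013) and HLA-DRA (-1.34, SE 0.19, adjusted p = 0.026) were called by limma, and the invariant chain gene CD74 had -0.55 (SE 0.20, adjusted p = 0.37). The HLA-DRB probes are uncertain because these genes are nearly identical in sequence. The median stayed between -0.96 and -0.63 without the filter, with 34 added, with cyclic loess and with each array left out. Of 6 class I genes none was called, none reached an unadjusted p under 0.05, and the median was -0.06, which changed sign under some of these settings. A set test of genes picked for their values decides nothing and is not given.

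KISS1, a metastasis suppressor gene that encodes kisspeptin, went from 9.59 ± 0.05 to 11.51 ± 0.14 (log2 fold change 1.92, adjusted p = 0.0035). SCG5, a secretory granule chaperone gene, had 2.20 (adjusted p = 0.0035), and TNFRSF11B, which encodes the decoy receptor osteoprotegerin that limits bone resorption, had 1.69 (adjusted p = 0.0082). FURIN, a protease that processes the TGFβ precursor, had 1.43 (adjusted p = 0.029). These genes lie outside the fixed lists. The collagen genes COL27A1 and COL16A1, which the fixed matrix list left out, rose by 1.31 and 0.99.

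Of the patterns weighed below, the tests of the difference between the TGFβ arrays, of cultures within a group and of neighbouring genes were chosen after the result was seen. The level-matched and the left-out-array tests of the mitotic list were written before.

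The risen genes lay higher on TGFβ replicate 2 than on replicate 1, by a median of 0.26 on the log2 scale and in 53 of 68 genes. Level-matched sets of uncalled genes gave medians between -0.08 and 0.08 in 95% of 10000 draws, which argues against a signal-level trend at the matched levels. The sets were matched on the average of the control and TGFβ means. Risen genes lay above that average on the TGFβ arrays, so a trend at their level there was not tested. The control arrays differed by a median of only 0.01 in the same genes, which argues against a shift shared by the replicate numbers for the risen genes only. Across all tested probes the same-numbered arrays did deviate together (r = 0.33). The fallen genes differed by -0.0691 between the TGFβ arrays, within the matched range of -0.10 to 0.10. They were higher on control replicate 2 than on control replicate 1 by 0.24, outside the matched range of -0.08 to 0.12. A stronger response in replicate 2 cannot be told apart from other differences between replicates: between same-numbered arrays the median change was 1.35 and 1.60 in risen genes and -1.18 and -1.41 in fallen genes, but no label says that a number marks a shared culture.

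The mitotic genes were lower with TGFβ by a median of -0.37, and a signal-level trend between the groups is argued against, since level-matched random lists lay between -0.09 and 0.06. No single array carried the shift, since the median stayed at -0.22 or below with each array left out. A chance difference between cultures of 1 group cannot be told apart from an effect of TGFβ, because each group has only 2 arrays. The smallest median between a TGFβ and a control array was -0.18, while the TGFβ arrays differed from each other by -0.27, and the S phase list moved with the replicate number (-0.28 between control arrays, -0.26 between TGFβ arrays). What lowered these transcripts was not tested.

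In the order of tested genes along the chromosomes, called genes followed each other more often than random placement gave. Untested genes may lie between such neighbours. Among 10669 tested genes with a position, 5 neighbouring pairs were called in the same direction, against a mean of 0.65 and a central 95% range of 0 to 3 over 10000 random placements (1-sided permutation p = 6.0e-04). The pairs were COL4A1 with COL4A2, CGB1 with CGB5, UCN2 with COL7A1 and NEDD9 with ADTRP, all higher, and PLLP with CX3CL1, both lower. Probes shared by near-identical genes may explain CGB1 with CGB5, but 3 pairs do not share the start of their symbols, still above the central range of 0 to 2 (p = 0.024, permutation). The pattern was seen before these tests were chosen, so both p-values only describe it and give no independent support. Whether neighbours share regulatory elements that respond to TGFβ was not tested.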
